A study of Mus musculus with 3 samples.

How the data were processed

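Mouse intestinal mesenchyme was profiled by single-cell RNA sequencing in 3 libraries, 1 per group: whole mesenchyme, Lepr+ before IR and Lepr+ after IR. Per the labels' protocols, the intestinal mesenchyme was digested to single cells, Epcam-CD45-fvd450- cells were sorted for whole mesenchyme and GFP+ cells for the Lepr+ libraries, and 10x Genomics 3' v2 libraries were made. The animals were 8 weeks old; how many were pooled per library is not given in the sources used here. The labels do not expand IR, and their treatment entry is the same for the library after IR as for the others. Groups were taken from the sample titles.

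The deposited matrices hold UMI counts per gene and barcode, whole numbers with no normalization, as an unfiltered matrix of 737280 barcodes and a filtered matrix per library. Per the submitters' processing notes, the counts were made by the authors with Cell Ranger 2.0.1 against mm10. Per the file headers, the whole mesenchyme matrix was written by software version 3.0.2, and the headers of the Lepr+ matrices name no version. The whole mesenchyme matrices list 31053 gene identifiers and the Lepr+ matrices 27998, of which 27514 are shared, 1027 of these with another symbol. A difference in annotation or counting version can move genes with near-identical copies, so ribosomal pseudogene-like genes are called uncertain. The step that chose the filtered barcodes is not given in the sources used here. The filtered matrices held 89.5%, 66.4% and 68.1% of all UMIs in the whole mesenchyme, before IR and after IR libraries, and their smallest barcodes held 500, 2148 and 3694 UMIs.

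The gene lists, cell type markers, cell filter, clustering settings, rule for named genes and most alternatives were fixed before the data were examined; the exceptions are named here and in the closing sections. Cells with at least 500 detected genes and at most 10% mitochondrial UMIs were kept. Doublets were called per library with the scrublet method in scanpy at an expected rate of 0.8% per 1000 cells and removed (200, 13 and 19 barcodes, or 2.50%, 0.541% and 0.808%). This left 7614, 2301 and 2234 cells. Counts on shared identifiers were scaled to 10000 per cell and log-transformed, and 2000 variable genes chosen with the library as batch key gave 30 principal components, 15 neighbours and 29 Leiden clusters at resolution 1, without integration. As the libraries were not integrated, a cluster mostly of 1 library may stand for that library. Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9 were used, with R 4.3.3 and edgeR 4.0.16 for TMM factors.

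Clusters were named from the fixed markers of 16 cell types and 5 fibroblast subclasses. A marker counted if at least 20% of the cluster's cells held a UMI of it and its mean was at least 3 times the lower quartile over clusters and at least 20% of the highest cluster's. A name needed 3 counted markers and no other type with more markers among the cluster's top 10 genes by fold, which had to be present in 25% of its cells. Of the types with 3 counted markers, that with the largest share of its markers counted was taken. Clusters more than 3 times shallower than the median cell of each of their libraries stayed unnamed if none of their type's markers was among those 10. These naming thresholds were set after the data were seen; the markers were not changed. Fibroblast-like cells numbered 1816, 632 and 1367 in the 3 libraries, holding 7836646, 2628818 and 12353454 UMIs.

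Expression was compared on UMIs summed over a class of cells and given as CPM with exact Poisson intervals, and differences as the log2 of CPM plus 5 in one library over CPM plus 5 in the other. Ratios carry exact binomial 95% intervals and cover counting error only. Whole mesenchyme against Lepr+ values used the shared identifiers (7813534 and 2614108 UMIs in fibroblast-like cells), while levels within a library and the comparison after against before IR used all identifiers of that library, which moves CPM slightly. With 1 library per group, no test, p-value or count of changed genes was computed from cells. Where a gene had no UMI, a floor of 3 counts set the limit of its fold difference.

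Named genes were, per comparison, the 12 highest and the 12 lowest log2 ratios among the compared genes with at least 50 CPM in either library, an absolute log2 of at least 1 and the same sign in each fibroblast subclass with 50 or more cells in both libraries, leaving out mitochondrial, ribosomal protein, haemoglobin, Xist, Y-linked, Malat1 and Neat1 genes. Added were the 2 highest and 2 lowest members of each list with at least 20 CPM, and always Lepr, Igf1 and Igf1r. In the whole mesenchyme library, niche factors with at least 50 CPM in any class were named, except that a gene that met this rule is not reported here. Other list members given as examples, and genes that lead clusters, were chosen after their values were seen. The 16 lists were the leptin and IGF axis, stem cell niche factors, BMP ligands and response, extracellular matrix, p53 targets, inflammatory chemokines and cytokines, interferon response, class I antigen presentation, complement, immediate early, heat shock, cell cycle, contractile, TGF beta and fibrosis, adipogenic and lipid, and glycolysis genes. A list's median over members with at least 20 CPM in either library was placed among 10000 random lists matched on size and on mean expression in 20 bins, as a description of these libraries.

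Shares of cells with a UMI were also computed after thinning each cell to 2000 or 1000 UMIs, beside glial-like (whole mesenchyme) or B or plasma-like cells (Lepr+ libraries) as background. Free RNA was profiled from barcodes with 1 to 10 UMIs. Its share in fibroblast-like cells was set from the marker list of another cell type that gave the lowest share among lists with at least 100 UMIs in that profile: 1.49% (erythroid), 0.624% (erythroid) and 5.79% (lymphatic endothelial). As these lists differ between libraries, a share from B or plasma markers in every library (2.73%, 8.86% and 6.56%) was added after seeing the data. That list matched 7 genes in the whole mesenchyme library but 6 in the Lepr+ libraries, as Igkc is outside the shared identifiers. It also holds Ptprc, which is a myeloid marker too. These shares are thus not on a fully common basis either.

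The calculation was tested on counts simulated as Poisson draws, with 200 genes changed by known folds. The simulation held counting error alone, with no variation between cells, animals or libraries. It thus checks the calculation and gives no error rate for a difference between 2 real libraries. For Lepr+ before IR against whole mesenchyme, 97% of 100 genes changed by a log2 of 1 and 92% of 100 changed by 2 came within 0.25 of the true value, and 0% of 2538 unchanged genes at 50 CPM or more reached an absolute log2 of 1. For after against before IR these were 97%, 93% and 0% of 2441 genes. The true ratio lay inside the 95% interval for 95% and 96% of changed genes in the first and 96% and 97% in the second. The real comparisons had been run once before this simulation was added.

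Alternatives were other cell filters, doublets kept, separate clustering, other resolutions, TMM factors, totals without mitochondrial and ribosomal protein genes, free RNA subtracted, means of per-cell CPM, pseudocounts of 1 and 20 CPM, subclasses weighted equally, all cells, no filter on list members, and thinning. Added after seeing the data were the second free RNA share, the whole mesenchyme library as baseline for the library after IR, in the pooled class and within lamina propria cells, lamina propria cells alone before IR, and the comparison of myeloid-like cells. Gene positions come from the GENCODE M21 annotation of GRCm38.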

Results

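Single-cell transcriptomes were collected from mesenchymal cells of the mouse intestine at 8 weeks of age with droplet capture and 3' v2 chemistry, which counts transcripts by unique molecular identifiers (UMIs). There were 3 libraries, 1 per group. The whole mesenchyme library came from wild-type mice by sorting cells negative for the epithelial marker Epcam, the leukocyte marker CD45 and the dye fvd450. The other libraries came from Lepr-Cre; R26-mTmG mice, in which cells that have expressed Cre, and their descendants, carry membrane GFP. The GFP+ cells were sorted and are called Lepr+ cells here. Of these libraries 1 was taken before and 1 after a step that the labels call IR without expanding it, and the treatment label of all 3 libraries reads untreated. The series title places the cells in an axis of leptin, Igf1 and the Igf1 receptor, so Lepr, Igf1 and Igf1r were read in every library.

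The cell-containing barcodes numbered 8013 in the whole mesenchyme library, 2404 in the Lepr+ library before IR and 2351 in the Lepr+ library after IR. They held 22423978, 13153155 and 20939323 UMIs, with medians of 2269, 4521.5 and 7601 per barcode. The smallest barcodes held 500, 2148 and 3694 UMIs. After filters and removal of called doublets, 7614, 2301 and 2234 cells remained. With 1 library per group no difference below has a replicate check, so no test was run. Intervals are 95% intervals (exact Poisson for sums of UMIs, exact Clopper-Pearson for shares) and cover counting error only. Fold differences on the log2 scale are of CPM plus a pseudocount of 5, which understates the difference of low genes.

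In the whole mesenchyme library, blood endothelial-like cells were the most frequent class at 55.6% (54.4 to 56.7), and fibroblast-like cells followed at 23.9% (22.9 to 24.8; 1816 of 7614 cells). Lymphatic endothelial-like cells made up 6.96%, smooth muscle-like cells 4.44%, pericyte-like cells 3.57% and glial-like cells 1.22%. Immune classes together made up 0.538% (0.387 to 0.730) under the CD45-negative sort. Among fibroblast-like cells, 60.1% were trophocyte-like, a submucosal class that expresses Grem1, 23.2% adventitial, 14.6% lamina propria and 2.04% telocyte-like. Another 3.84% of cells stayed unnamed, in clusters led by Stmn2, Nebl and Clu or by Madcam1, Selp and Ackr1. Clu and Sox17 were among the top 10 genes both of the first of these and of blood endothelial-like cluster 1. Whether the unnamed cells belong to that class was not tested, so its share may be understated. Removing cells under 1000 genes or over 5% mitochondrial UMIs gave 30% fibroblast-like cells.

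Lepr, the leptin receptor gene, had its highest level in fibroblast-like cells of this library, at 60.5 CPM (55.2 to 66.2), and was lower in lymphatic endothelial-like (31.4 CPM), smooth muscle-like (14.6 CPM) and blood endothelial-like cells (12.3 CPM). No Lepr UMI was seen in 93 glial-like cells, which allows a share of cells with a UMI of up to 3.89%. Lepr UMIs were present in 20.7% (18.9 to 22.6) of fibroblast-like cells at a median depth of 4218 UMIs, against 2354 UMIs in glial-like cells. With each cell thinned to 2000 UMIs, which left out 190 fibroblast-like and 32 glial-like cells, the shares were 10.1% and 0%. Igf1, which encodes a secreted growth factor, was highest in smooth muscle-like cells (462 CPM, 428 to 499) and second in fibroblast-like cells (197 CPM, 187 to 207). Lymphatic endothelial-like cells held 4.65 CPM of Igf1. Igf1 UMIs were present in 65.4% of smooth muscle-like, 47.9% of fibroblast-like and 4.30% of glial-like cells, and in 48.8%, 32.2% and 1.64% after thinning to 2000 UMIs. Within fibroblast-like cells Igf1 was 243 CPM in trophocyte-like, 237 CPM in lamina propria and 102 CPM in adventitial cells. Igf1r, its receptor gene, was 90.4 CPM (55.9 to 138) in glial-like, 83.6 CPM (69.3 to 100) in smooth muscle-like and 56.9 CPM (51.8 to 62.4) in fibroblast-like cells. The glial-like value rests on 21 UMIs.

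Factors known to act on intestinal stem cells were spread over several classes of the whole mesenchyme library. The BMP antagonist Grem1 was highest in fibroblast-like cells (523 CPM), with 780 CPM in the trophocyte-like subclass. The Wnt modulator Sfrp1 was also highest there (1172 CPM), with 2514 CPM in lamina propria cells. The Wnt ligand Wnt2, the Wnt amplifier Rspo3 and the cytokine Il33 were highest in lymphatic endothelial-like cells, at 324, 454 and 527 CPM. Fibroblast-like cells held 105 CPM of Rspo3 and 332 CPM of Il33. Smooth muscle-like cells had the highest Fgf7 (109 CPM) and Ereg (63.4 CPM), the last an epidermal growth factor receptor ligand.

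The Lepr+ sort before IR was compared with the whole mesenchyme library to ask what the Lepr-marked cells contain. Myeloid-like cells made up 61.9% (59.9 to 63.9) of the GFP+ library, against 0.276% (0.171 to 0.421) of the CD45-negative library. Fibroblast-like cells made up 27.5% (25.7 to 29.3) against 23.9%. No blood endothelial-like or glial-like cell was found among 2301 cells, which allows shares of up to 0.160%, against 55.6% and 1.22%. Outside immune and epithelial classes, 88.3% (85.7 to 90.5) of Lepr+ cells were fibroblast-like, against 24.0% (23.0 to 25). The sorts differ in their gates, and the CD45 gate alone can set the immune share. The smallest barcodes differ too, at 500 UMIs in the whole mesenchyme library and 2148 before IR. In whole mesenchyme, 427 of 530 lymphatic endothelial-like and 190 of 1816 fibroblast-like cells held under 2000 UMIs. A higher cut-off can thus lower endothelial shares and raise the fibroblast-like share before IR, and its part was not tested. Clustering each library separately gave 48.2% myeloid-like cells.

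**Figure D1:**
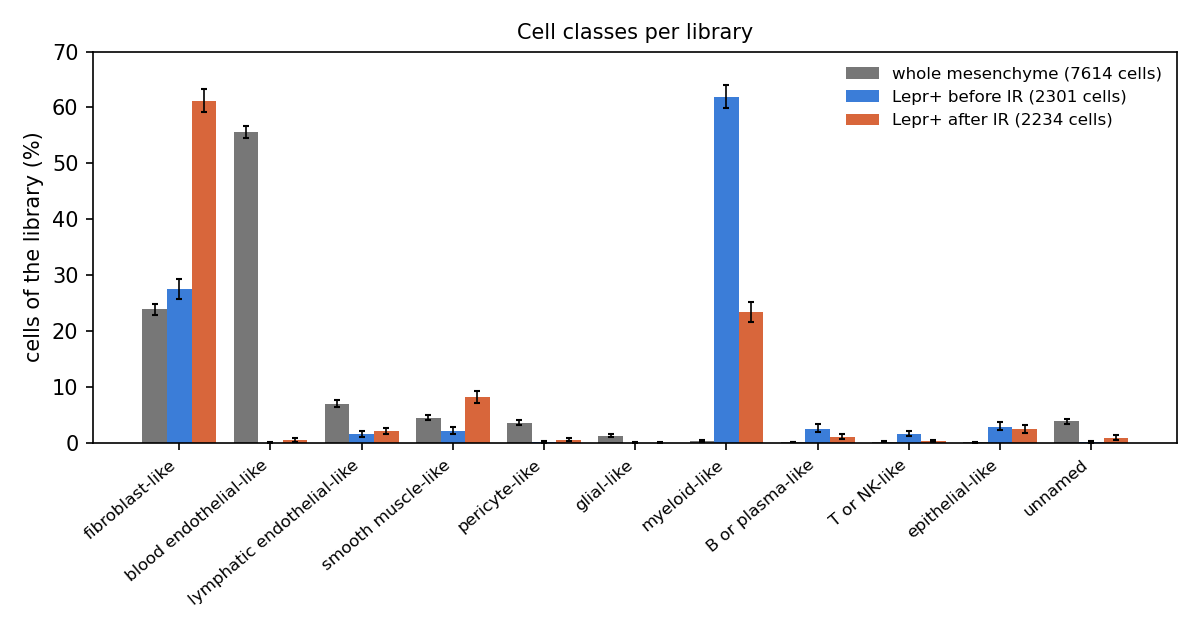
Share of cells per named class (y axis, percent of the cells kept in a library) in the 3 libraries, with 95% Clopper-Pearson intervals that cover counting error only. Blood endothelial-like cells are the tallest class of the whole mesenchyme library at 55.6%, myeloid-like cells of the Lepr+ library before IR at 61.9% and fibroblast-like cells of the Lepr+ library after IR at 61.2%.

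Within the fibroblast-like class, 76.9% of the Lepr+ cells before IR were lamina propria and 21.7% trophocyte-like, against 14.6% and 60.1% in the whole mesenchyme library. Adventitial cells were 0.158% against 23.2%. Cluster 6 held most lamina propria cells of both libraries (462 and 256 cells), but trophocyte-like cells lay in cluster 17 before IR (131 cells) and in clusters 5 and 14 in the whole mesenchyme library (866 and 223 cells), so a cluster of that class may stand for its library. Lepr was 2.54-fold higher (2.22 to 2.91) in Lepr+ fibroblast-like cells before IR, at 154 against 60.7 CPM. It was higher by 2.01 on the log2 scale within lamina propria cells and by 1.34 within trophocyte-like cells, against 1.28 in the pooled class. Lepr UMIs were present in 45.9% of these cells (26.9% after thinning to 2000 UMIs) and in 3.45% of B or plasma-like cells, at median depths of 3899 and 5108 UMIs. Igf1 was 1.98-fold higher (1.83 to 2.15), at 392 against 197 CPM. By subclass its log2 difference was 0.89 in lamina propria cells and -0.22 in trophocyte-like cells. Igf1r differed by 1.17-fold (0.973 to 1.39), which counting error alone spans, and its log2 difference was -0.42 in lamina propria and -0.61 in trophocyte-like cells.

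The acute-phase gene Saa3 led the genes that were higher in Lepr+ fibroblast-like cells before IR, at 744 against 0.256 CPM (1944 against 2 UMIs), a ratio of 2905 with an interval of 803 to 24007. The matrix protease Mmp10 followed at 1202 against 7.55 CPM, a ratio of 159 (123 to 210). The MHC class II genes H2-Ab1 and H2-Aa and their invariant chain gene Cd74 were higher by 5.11, 4.78 and 4.73 on the log2 scale, and the complement gene C1qa, a macrophage marker, by 4.85. The myeloid markers summed to 950 CPM in these cells against 20.8 CPM. Subtracting free RNA at the share set by B or plasma markers, an alternative chosen after seeing the data, turned these 4 genes to -1.31, -0.97, -2.48 and -0.48. That share was 8.86% before IR, while the 4 genes stood at 6.53% to 8.10% of their free RNA level. No UMI of them was thus left before IR, so the subtraction sets the sign, and no reversal is read from it. The remaining genes of the 12 with the highest ratios were Tonsl (5.02), AY036118 (5.11) and the ribosomal protein pseudogene-like Gm10036, Gm10073, Gm9493 and Gm9844 (6.53, 5.96, 5.78 and 5.73). The last 4 may share reads with near-identical copies, which was not tested, and are uncertain. They were also higher by 6.13 to 6.52 in lymphatic endothelial-like cells, as were Tonsl (5.66) and AY036118 (3.86). Of all 12 genes, 11 were at least 2-fold higher in those cells (35 before IR against 530) and 12 in smooth muscle-like cells. Saa3 rests on 2 against 0 UMIs in each of these classes.

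The 12 genes with the lowest ratios were Fabp4, Dusp1, Cdkn1a, Plvap, Rgcc, Jund, Emcn, Flt1, Scand1, Has1, Klf9 and Nenf. Dusp1, an immediate early phosphatase gene, was 49.3 against 1025 CPM, a log2 difference of -4.24. The cell cycle inhibitor gene Cdkn1a was 23.0 against 427 CPM (-3.95). Jund was 156 against 2022 CPM (-3.66). Plvap, Emcn and Flt1 are blood endothelial markers, and those markers summed to 19.4 CPM before IR against 542 CPM in whole mesenchyme fibroblast-like cells. Flt1 had no UMI before IR against 432, at least 48.2-fold lower, and Rgcc none against 486, at least 54.2-fold lower, both against a floor of 3 counts over the class. Rgcc is among the top genes of blood endothelial-like clusters 0 and 3. Blood endothelial markers in whole mesenchyme fibroblast-like cells stood at 6.01% of their share in barcodes with 1 to 10 UMIs. Free RNA of blood endothelial cells was not tested as a source of these genes. Fabp4, a lipid carrier of capillary endothelium and adipocytes, was at 4 against 1120 UMIs (-4.51). Of these 12 genes, 10 were also lower in lymphatic endothelial-like cells, 8 of them by 2-fold, and 11 in smooth muscle-like cells, all 11 by 2-fold. Among the 8, Rgcc (0 against 24 UMIs) and Flt1 (0 against 25 UMIs) have intervals that span no difference. In lymphatic endothelial-like cells Scand1, Jund, Klf9 and Nenf stood at -2.27, -2.37, -2.52 and -2.49.

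The mix of subclasses enters these pooled values. The 24 genes above were chosen with the same sign in both subclasses, so their direction there is set by the rule. Of 40 other named genes at least 2-fold apart in the pooled class, 11 were so in the same direction in both lamina propria and trophocyte-like cells, 11 in neither, and 11 had the other sign in at least 1 of them. Sizes also differed by subclass: Mmp10 was 4.52 in lamina propria and 1.08 in trophocyte-like cells against 6.59 pooled, Saa3 7.51 and 2.12 against 7.15, and Has1 -0.71 and -0.70 against -3.50.

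By gene list, immune-related groups stood higher in Lepr+ fibroblast-like cells before IR. Each percentile places a list's median among those of 10000 random lists matched on size and expression, and counts of genes at 2-fold are on the log2 scale with the pseudocount. Of 21 measured inflammatory chemokine and cytokine genes, 13 were at least 2-fold higher and 3 at least 2-fold lower (median log2 1.44, percentile 100). Ccl8 (32.4-fold, 24.3 to 44.0) was higher and Cxcl1 (0.140-fold, 0.116 to 0.167) lower, but Cxcl1 was 0.11 higher on the log2 scale within lamina propria cells. Of 20 interferon response genes, 11 were 2-fold higher and 0 lower (median 1.04, percentile 100), led by Irgm1 (8.79-fold) and Ifitm1 (5.12-fold). Within lamina propria cells alone that median was 0.69. All but 1 of the 9 class I antigen presentation genes were 2-fold higher (median 1.5, percentile 100), Tap2 5.21-fold and Psmb9 3.48-fold. Within lamina propria cells alone that median was 1.06. Complement genes had a median of 0.45 (percentile 98.0), with 1 of 8 above 2-fold, C4b (2.23-fold in CPM). Cfb was 2.01-fold in CPM but 0.97 on that log2 scale. Myeloid markers differed beside these groups as given above.

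Immediate early genes, which switch on within minutes of a stimulus, formed the lowest list. Of 15 genes 13 were at least 2-fold lower and none higher (median -2.76, percentile 0). The median was -1.05 within lamina propria cells alone, and Nr4a1 was -0.68 pooled but higher by 1.40 within lamina propria and by 1.52 within trophocyte-like cells. Fos was 361 against 2209 CPM and Egr1 156 against 1252 CPM. The p53 target list had a median of -0.65 (percentile 0.310), with 4 of 9 genes 2-fold lower, Cdkn1a and Btg2 (0.205-fold) among them. Over all 20 genes of the list, without the filter on level, the median was -0.23. On the log2 scale Btg2 was -2.24 pooled, -0.72 within lamina propria and -0.75 within trophocyte-like cells. Among RNA quality measures, mitochondrial UMIs made up 3.05% against 2.39% and ribosomal protein genes 16.8% against 19.1%. Malat1 stood at 44318 against 48171 CPM and Neat1 at 226 against 426 CPM.

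Contractile genes were higher in 7 of 8 cases by 2-fold (median 1.57, percentile 100), with Acta2, smooth muscle actin, at 632 against 85.5 CPM, and smooth muscle markers as a set at 974 against 212 CPM. Pericyte markers stood at 696 against 146 CPM in the same cells. Within lamina propria cells alone the contractile median was 0.87. Acta2 was higher by 1.5 within lamina propria cells but stood at -0.32 within trophocyte-like cells, and Tagln at 0.86 and -0.87. Over all cells the contractile median turned to -1.46 and that of complement genes to -0.43, since the mix of classes then enters. BMP ligands and response genes had a median of -0.54 (percentile 1.67) with 2 of 6 higher and 2 lower: Bmp5 (6.03-fold) and Bmp4 (2.49-fold) were higher, Id2 (0.369-fold) and Bmp1 (0.438-fold) lower. Within lamina propria and trophocyte-like cells the log2 differences were 0.51 and -0.13 for Bmp5, 0.65 and 0.05 for Bmp4, and 0.78 and -1.31 for Id2, which thus turned in lamina propria cells. Within lamina propria cells this median turned to 0.41. TGF beta and fibrosis genes had a median of -0.44 (percentile 1.05; 3 of 13 higher, 3 lower), which became 0.04 with subclasses weighted equally. Ltbp1 was 3.99-fold higher and Tgfb1 0.0799-fold.

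The leptin and IGF list had a median of 0.23 (percentile 88.2) and a mean of -0.17, since 3 of 13 genes were 2-fold higher (Lepr, Igfbp5 and Igfbp3) and 3 lower (Igfbp6, Igfbp7 and Socs3). Niche factors had a median of 0.04 (percentile 57.9; 3 of 10 higher, 1 lower), with Ereg 9.56-fold and Hgf 7.39-fold higher and Il33 0.453-fold. Within lamina propria and trophocyte-like cells Ereg was higher by 1.06 and 0.09 and Hgf by 1.02 and 0.64 on the log2 scale. Extracellular matrix genes had a median of 0.05 and a mean of -0.05 (percentile 52.0; 2 of 25 higher, 4 lower), between Tnc (11.6-fold) and Mfap5 (0.206-fold). Tnc was 1.25 in lamina propria and -1.01 in trophocyte-like cells, and Mfap5 -1.61 and -0.74. Heat shock genes had a median of 0.21 and a mean of -0.12 (percentile 78.9; 1 of 11 higher, Hspa1b, and 2 lower). Cell cycle genes had a median of 0.98 (percentile 95.8; 2 of 4 higher), of which Top2a and Birc5 turned to -0.87 and -0.21 within lamina propria cells and the median to -0.12. Adipogenic and lipid genes had a median of 0.62 and a mean of -0.12 (percentile 95.9; 1 of 5 higher, 1 lower). Glycolysis genes had a median of -0.01 (percentile 30.9; 1 of 9 higher, 1 lower), with Ldha 2.63-fold higher.

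The whole mesenchyme and Lepr+ libraries also differ in genotype, in sort and in the gene annotation their matrices were counted with, 31053 against 27998 gene identifiers, so none of these can be separated from the Lepr+ label. Over all cells of each library the Lepr difference was 0.35 and the interferon median 0.16.

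The Lepr+ libraries after and before IR were then compared. Fibroblast-like cells made up 61.2% (59.1 to 63.2) of GFP+ cells after IR against 27.5% before, and myeloid-like cells 23.4% (21.7 to 25.2) against 61.9%. Smooth muscle-like cells made up 8.10% (7.0 to 9.31) against 2.04%. Outside immune and epithelial classes, the fibroblast-like share was 83.8% (81.9 to 85.6) after IR against 88.3% (85.7 to 90.5) before. It was thus not higher after IR once those classes were left out. The smallest barcodes held 3694 UMIs after and 2148 before IR, which can also move these shares. Igf1 in fibroblast-like cells was 3.31-fold higher (3.11 to 3.53) after IR, at 1289 (1269 to 1309) against 390 CPM (366 to 414). Saa3 was 24.9-fold higher (23.8 to 26.1), at 18433 against 739 CPM. Lepr was 0.459-fold (0.408 to 0.518), at 70.4 against 153 CPM, and Igf1r 0.534-fold (0.447 to 0.641), at 35.4 against 66.2 CPM.

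**Figure D2:**
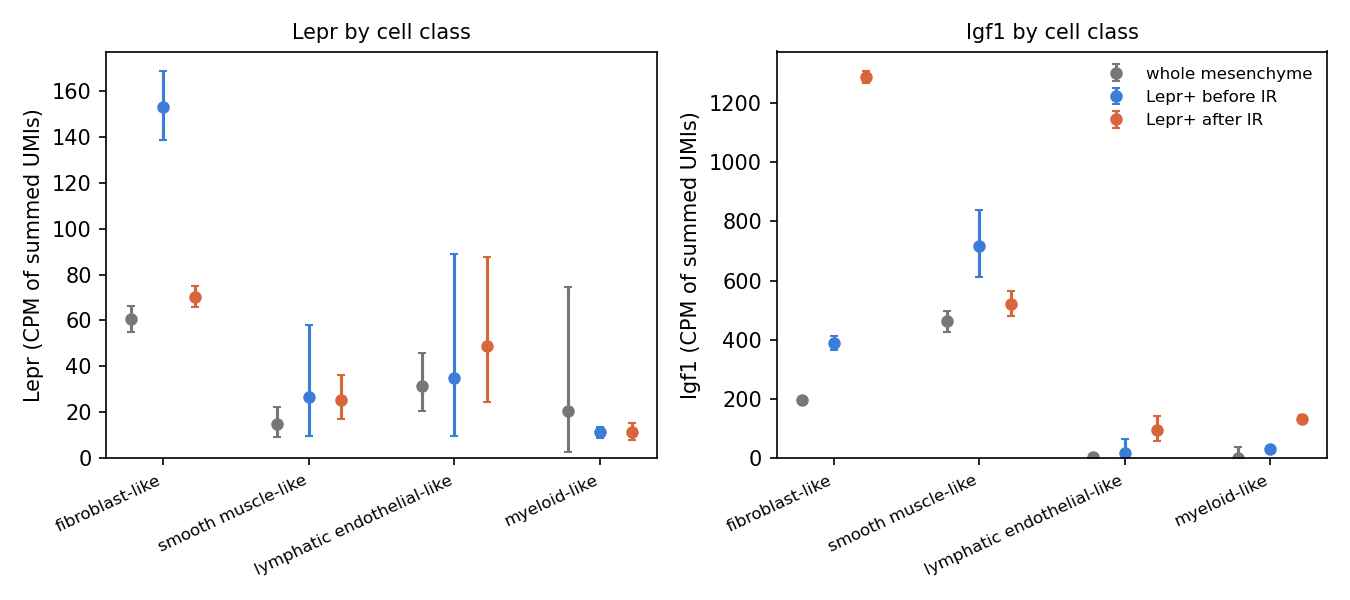
Lepr (left) and Igf1 (right) in CPM of summed UMIs (y axis) for 4 classes in the 3 libraries, with exact Poisson 95% intervals that cover counting error only. In fibroblast-like cells Igf1 stands at 197, 390 and 1289 CPM in the whole mesenchyme, before IR and after IR libraries, and Lepr at 60.5, 153 and 70.4 CPM.

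Among fibroblast-like cells, lamina propria cells were 76.9% before and 68.8% after IR, in cluster 6 before (462 cells) and in cluster 4 after (883 cells). A further 30.9% after IR (422 cells) and 0.949% before (6 cells) formed cluster 9, led by Saa3, Cxcl13 and Cpxm1, which the naming rule left without a subclass. The genes that lead clusters 4 and 9, Timp1, Cxcl5, Cxcl14, Saa3 and Mt2 among them, differ between the libraries as a whole, so the sizes of these clusters and those genes are not independent measures. Only lamina propria cells numbered 50 or more in both libraries. Within them Igf1 was higher by 1.67 and Saa3 by 3.91 on the log2 scale, against 1.71 and 4.63 in the pooled class, and Lepr stood at -0.83 against -1.07. With the whole mesenchyme library as baseline Lepr after IR was higher by 0.20 in the pooled class and by 1.17 within lamina propria cells.

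Igf1 UMIs were present in 95.7% (94.5 to 96.7) of fibroblast-like cells after IR and in 63.0% (59.1 to 66.8) before, and in 78.9% and 46.5% after thinning to 2000 UMIs. Among B or plasma-like cells, which should lack Igf1, 27.3% of 22 (10.7 to 50.2) held an Igf1 UMI after IR and 6.90% of 58 (1.91 to 16.7) before. After thinning these shares were 9.09% (1.12 to 29.2) and 3.45% (0.420 to 11.9), and in both cases the intervals overlap. Median depths of fibroblast-like cells were 8686 and 3899 UMIs, and of B or plasma-like cells 5399 and 5108. The share with a Lepr UMI was 41.5% after and 45.9% before IR, or 14.3% and 26.9% after thinning, with 0 of 22 B or plasma-like cells after IR (a limit of 15.4%). In smooth muscle-like cells Igf1 was 521 CPM (481 to 564) after IR against 718 CPM (611 to 838) before, in partly different clusters (20, 25 and 11 against 11). In myeloid-like cells it was 132 CPM (120 to 145) against 30.1 CPM (26.4 to 34.2), in clusters 8 and 2. After IR B or plasma-like cells held more, 326 CPM (236 to 439), from 43 UMIs in 6 of 22 cells, and lymphatic endothelial-like cells 93.6 CPM (57.9 to 143). The share of cells with an Igf1 UMI was instead higher in myeloid-like cells, 48.4% (44.0 to 52.8), or 24.1% (20.5 to 28.0) after thinning, so no order is read from these values.

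TMM factors raised log2 ratios in this comparison by a median of 0.14 over genes with at least 20 CPM in either library. On that scaling Igf1 was higher by 1.87 and the interferon list by 0.74. Among the genes named here, Il33, Eno1 and Lpl lie close to 0 and change sign with it. The 12 genes with the highest ratios in fibroblast-like cells after IR included the acute-phase and iron-binding genes Saa3, Lcn2 (126 against 1.90 CPM) and Hp (83.5 against 2.66 CPM), the protease inhibitor gene Timp1 (22.9-fold, 19.5 to 27.0), the metallothionein gene Mt2 (12.7-fold, 11.6 to 14.0) and the IGF-binding gene Igfbp7 (11.9-fold, 11.4 to 12.5). The others were Scand1, Nme2, Hist1h2ap, Lars2, Gm26870 and Gm15056. Of the 12, 10 were also higher in lymphatic endothelial-like cells (45 after and 35 before IR), 9 of them by 2-fold. Of the 9, Hp rests on 2 against 0 UMIs, and the interval of Lars2 (2.36-fold, 0.877 to 7.94) spans no difference. Among these were Igfbp7 by 5.02, Saa3 by 4.60, Mt2 by 4.41, Nme2 by 2.98, Scand1 by 2.58 and Timp1 by 2.56. In smooth muscle-like cells all 12 were higher, 11 of them by 2-fold, and Saa3 by 4.82. Against the whole mesenchyme library as baseline, chosen after seeing the data, 10 of these 12 were still at least 2-fold higher, Saa3 by 11.78 and Timp1 by 3.59, while Igfbp7 was higher by 0.85 and Scand1 by 0.52. Within lamina propria cells Hist1h2ap also lay under 2-fold on that baseline, at 0.81. Of all 32 named genes at least 2-fold higher after IR, 21 were so against that baseline and 4 had the other sign, or 23 and 2 within lamina propria cells. Of 18 lower genes 11 were so and 5 had the other sign, or 13 and 5. Nme2 and Hist1h2ap belong to families of near-identical copies and are uncertain.

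The 12 genes with the lowest ratios after IR were Gm42726 (-4.01), Tppp3 (-3.74), Ms4a4c, AY036118, Creb5, Angptl1, C1qtnf3, H2-Ab1 (-2.67), Ackr4, S100a10, Cd74 and Selenbp1. Tppp3 was 50.4 against 735 CPM, and Ackr4, an atypical chemokine receptor gene among the trophocyte markers, 21.0 against 159 CPM. Trophocyte-like cells were 21.7% of the class before and 0.219% after IR, and within lamina propria cells Ackr4 was -0.66 against -2.66 pooled. Of 26 named genes at least 2-fold apart after IR that were not chosen with a rule on subclasses, 23 were so in the same direction within lamina propria cells. Ms4a4c, H2-Ab1 and Cd74 lead the myeloid cluster 2, and myeloid markers in fibroblast-like cells summed to 379 CPM after IR against 950 CPM before. Gm42726, AY036118, H2-Ab1 and Cd74 were higher after IR with the whole mesenchyme library as baseline, by 0.59, 2.29, 2.44 and 2.19.

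Of 24 inflammatory genes 10 were at least 2-fold higher after IR and 1 lower (median 0.79, percentile 100). Ccl7 was 490 against 46.0 CPM, Cxcl5 1281 against 201 CPM, and the exception was Cxcl12 (0.426-fold, 0.411 to 0.441). Of 20 interferon response genes 3 were 2-fold higher and 0 lower (median 0.58, percentile 100), Isg15 2.98-fold (2.72 to 3.26) and Ifitm1 2.14-fold. With the whole mesenchyme library as baseline the interferon median was 1.69 and the Igf1 difference 2.68, or 1.32 and 2.56 within lamina propria cells. Class I antigen presentation genes had a median of -0.20 (percentile 10.1) with 0 of 9 beyond 2-fold, and complement genes -0.38 (percentile 1.36) with 0 of 8, C3 being 1.69-fold higher. With that baseline these medians were 1.22 and 0.40, or 0.98 and 0.07 within lamina propria cells.

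The p53 target list had a median of 0.84 (percentile 99.99) with 4 of 11 genes 2-fold higher and 0 lower. Cdkn1a was 8.39-fold (6.50 to 11.0), Phlda3 5.23-fold (4.40 to 6.28), Bax 331 against 150 CPM and Mdm2 29.1 against 14.1 CPM. Immediate early genes had a median of 0.64 (percentile 99.99) with 4 of 15 higher, Dusp1 5.36-fold and Ier3 4.08-fold, but within lamina propria cells, the only subclass compared, that median was 0.0027. With the whole mesenchyme library as baseline Dusp1 stood at -1.94 and the immediate early median at -2.01, or -2.23 and -1.37 within lamina propria cells. On that baseline Cdkn1a was -1.13 in the pooled class but 0.16 within lamina propria cells, Phlda3 0.38 and 0.69, and Ier3 0.17 and 1.75. Heat shock genes had a median of 0.19 (percentile 93.7; 2 of 11 higher, 0 lower), with Hspb1 8.80-fold, which stood at -0.53 against the whole mesenchyme library within lamina propria cells. Within lamina propria cells after against before IR the heat shock median turned to -0.15. Among RNA quality measures, Malat1 was 18559 against 44318 CPM and Neat1 149 against 226 CPM, while mitochondrial UMIs (2.83% against 3.05%) and ribosomal protein genes (16.5% against 16.8%) lay close.

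Niche factors had a median of 0.50 (percentile 99.95; 3 of 13 higher, 0 lower). The epidermal growth factor family ligands Nrg1 (7.04-fold, 5.20 to 9.77) and Ereg (2.61-fold, 2.31 to 2.96) were higher. Grem1 was 0.815-fold, but within lamina propria cells its log2 difference turned to 0.13. The leptin and IGF list had a median of 0.12 (percentile 91.1) with 4 of 14 higher, Igf1, Igfbp4 (4.66-fold), Igfbp7 and Socs3, and 2 lower, Lepr and Igfbp6. BMP ligands and response genes had a median of 0.57 (percentile 99.6; 3 of 8 higher, 0 lower). The higher members were the response genes Id1 (3.47-fold), Id2 (2.64-fold) and Id3, while the ligands Bmp4 (0.667-fold) and Bmp2 (0.546-fold) were lower. With the whole mesenchyme library as baseline Bmp4 was higher by 0.72 and Id2 stood at -0.04, but within lamina propria cells Bmp4 was higher by 0.20 and Id2 by 2.04.

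Extracellular matrix genes had a median of 0.41 (percentile 99.98; 5 of 25 higher, 1 lower), with the collagen cross-linking enzyme gene Lox 3.79-fold and Col4a2 2.55-fold higher and Col14a1 0.463-fold. TGF beta and fibrosis genes had a median of 0.09 (percentile 86.5; 5 of 14 higher, 2 lower), with Tgfb1 21.6-fold (10.4 to 54.0, from 711 against 7 UMIs) and Tgfb2 0.322-fold. Against the whole mesenchyme library Tgfb1 was higher by only 0.70, or 0.90 within lamina propria cells, on the log2 scale. Contractile genes had a median of 0.26 (percentile 95.1; 1 of 8 higher), cell cycle genes 0.35 (percentile 97.9; 0 of 6), adipogenic and lipid genes 0.20 (percentile 86.4; 1 of 5, Cebpb) and glycolysis genes 0.34 (percentile 98.3; 1 of 10, Hk2 at 3.87-fold). Hk2 turned to -0.57 against the whole mesenchyme library, where it was 2.28 within lamina propria cells, and to -0.06 over all cells.

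**Figure D3:**
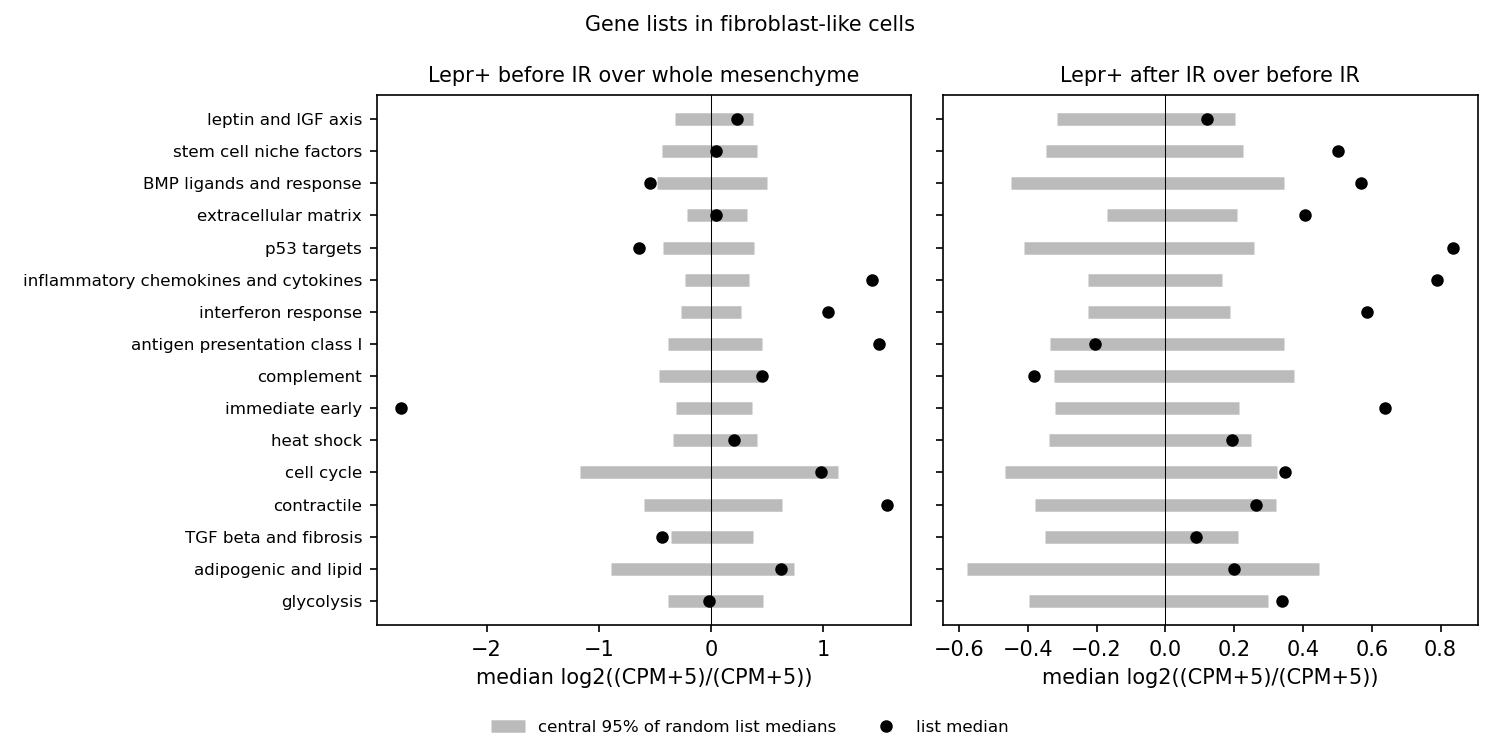
Median log2 ratio of each fixed gene list in fibroblast-like cells (points; x axis), for the Lepr+ library before IR over whole mesenchyme (left) and after over before IR (right), on separate scales. Grey bars span the central 95% of medians of 10000 random lists matched on size and expression; the immediate early median is -2.76 on the left and 0.64 on the right.

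Both Lepr+ libraries are single, so a property of the library before IR appears in both comparisons with opposite sign. Over all cells, Igf1 was higher after IR by 2.85 and Lepr by 0.22, against -1.07 for Lepr within fibroblast-like cells.

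Positions are given on mm10 (GRCm38). Igf1 (ENSMUSG00000020053) lies on chromosome 10 from 87858265 to 87937042, Igf1r (ENSMUSG00000005533) on chromosome 7 from 67952827 to 68233668, and Lepr (ENSMUSG00000057722) on chromosome 4 from 101717404 to 101815352. All 3 are protein-coding genes on the plus strand, and the counts are of transcripts captured at their 3' ends.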

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

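The tests of Lepr transcription in myeloid-like cells, of the subclass mix for Igf1 and of a shared shift for Igf1 or as the whole cause for the 12 highest genes were chosen after those results were seen. The other tests were written down before the values they measure were seen, on patterns found in the same data.

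Signal appeared in genes and barcodes that the comparisons of libraries do not use. In cells of the whole mesenchyme library, the immunoglobulin genes Igkc and Igha, which are outside the identifiers shared with the Lepr+ libraries, held 48476 and 19177 UMIs. Of these, 96.5% and 95.3% lay in the 7 B or plasma-like cells, and 16.9% and 10.5% of the 7614 cells held at least 1 such UMI. The 3539 identifiers listed for the whole mesenchyme library alone held 114658 UMIs, or 0.541% of its total. Outside the cell barcodes, defensin genes, which are products of Paneth cells of the epithelium, stood at 36992 CPM in the Lepr+ library before IR and at 15777 CPM after IR, against 971 CPM in the whole mesenchyme library.

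Myeloid-like cells made up 61.9% of the Lepr+ sort before IR, a sort without a CD45 gate. The tables argue against free RNA as the cause, since lymphatic endothelial-like cells of that library held myeloid markers at 3.59% of the share in myeloid-like cells. They also argue against droplets with a fibroblast and a myeloid cell, since myeloid-like cells held fibroblast markers at 1.30% of the share in fibroblast-like cells. Both values are limited, as the classes were named from these same marker lists after called doublets were removed. Lepr in the myeloid-like cells was 11.1 CPM (8.93 to 13.7), above the 2.63 CPM that free RNA at the B or plasma share would give, a level that rests on 16 UMIs, but within the interval of B or plasma-like cells themselves (5.0 CPM, 0.605 to 18.1). The share with a Lepr UMI was 4.56% (3.54 to 5.78) against 3.45% (0.420 to 11.9; 2 of 58 cells), so Lepr transcription and background cannot be told apart with so few background cells. Activity of Cre or GFP without Lepr, autofluorescence in the sort and a real Lepr history of these cells stay open and were not tested.

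Igf1, Saa3 and other genes were higher in fibroblast-like cells after IR than before. Free RNA is argued against. The lower log2 ratio after either subtraction stayed at 1.67 (1.59 to 1.77) for Igf1 and 4.58 (4.53 to 4.66) for Saa3. Another mix of the named subclasses as the whole cause is argued against by 1.67 (1.58 to 1.78) and 3.91 (3.85 to 3.98) within lamina propria cells. That name covered mostly cluster 6 before IR (462 cells) and cluster 4 after IR (883 cells), so the mix of cells within it was not held constant. Intervals of single genes in this paragraph are of count ratios without the pseudocount, with subtracted counts taken as exact. A shift of the library before IR shared by all cell types stays open as part of the cause for the 12 genes with the highest ratios. Their median in lymphatic endothelial-like cells was 2.57, or 2.78 over the 10 with a UMI there (single genes from 0.85 to 5.02). Free RNA or a response in those cells could give the same. Igf1 was higher by 2.14 in lymphatic endothelial-like cells (21 against 2 UMIs) and by 1.97 in myeloid-like cells, but stood at -0.46 in smooth muscle-like cells. For Igf1, too, that shift stays open as part of the cause. As the whole cause that shift is argued against for Igf1, which within lamina propria cells was 2.56 higher (2.39 to 2.78) after IR than in the whole mesenchyme library, which differs in genotype, sort and annotation, and for 8 of the 12 genes, whose intervals there lay above 2-fold, but not for Igfbp7 (0.46), Scand1 (0.31), Hist1h2ap (0.81) and Lcn2 (1.46, 0.99 to 2.53). An effect of IR stays among the open explanations, untested with 1 library per group.

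Genes also differed between Lepr+ fibroblast-like cells before IR and those of the whole mesenchyme library. Reads of the library after IR carried over by swapped indices are argued against for Saa3, since 0% of its 3512 UMIs before IR (upper limit 0.105%) lay in barcodes that were cells of the other library alone. A shift shared by cell types stays open. In lymphatic endothelial-like cells the 12 higher genes had a median of 3.95, or 4.04 over the 11 with a UMI there (single genes from 2.17 to 6.52). The 12 lower genes had a median of -2.32, or -2.37 over 11 (single genes from -4.10 to 0.90). For H2-Ab1, H2-Aa, Cd74 and C1qa, free RNA of myeloid cells may be the source. Their median share in fibroblast-like cells was 7.20% of that in near-empty droplets (single genes from 6.53% to 8.10%). The myeloid marker list, which itself holds C1qa, stood at 7.23%. For the endothelial genes Plvap, Emcn, Flt1 and Rgcc, lower before IR, free RNA of blood endothelial cells in the whole mesenchyme library stays open and was not tested. The Lepr+ label, genotype, sort and annotation stay open and were not separated by this design.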

How the results depend on the processing

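Chosen after the data were seen were the B or plasma share of free RNA, lamina propria cells alone and the whole mesenchyme library as baseline, pooled or within lamina propria cells, as was the choice of the 7 values in the next paragraph. No paired analysis was possible because each group has 1 library. Depth limits genes near the pseudocount, and all intervals are of counting error alone.

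Fibroblast-like cells of the whole mesenchyme library (23.9%) became 30.002% with the stricter cell filter and 22.4% with doublets kept, and those after IR (61.2%) became 64.5% with the stricter filter. Myeloid-like cells before IR (61.9%) became 59.8% at resolution 2 and 48.2% with separate clustering. For Lepr+ before IR against whole mesenchyme, Lepr (1.28) and the interferon median (1.04) became 2.01 and 0.69 in lamina propria cells alone, 1.11 and 0.91 with a pseudocount of 20 CPM, 1.60 and 0.79 with equal subclasses, and 0.35 and 0.16 over all cells. After against before IR, Igf1 (1.71) became 1.87 with TMM factors, 2.68 against the whole mesenchyme baseline, 2.56 against it within lamina propria cells and 2.85 over all cells, and the interferon median (0.58) became 0.74 with TMM factors, 1.69 against that baseline and 1.32 against it within lamina propria cells. All of these kept their direction.

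Among named genes at least 2-fold apart and list medians outside the central 95% of random lists, signs turned as follows for Lepr+ before IR against whole mesenchyme. Subtracting free RNA at the B or plasma share gave H2-Ab1 -1.31, C1qa -0.48, H2-Aa -0.97 and Cd74 -2.48. These signs are set by the subtraction, which left no UMI of these genes before IR. Lamina propria cells alone gave Id2 0.78, Cxcl1 0.11, Birc5 -0.21, Top2a -0.87, Hk2 1.20 and the BMP median 0.41. Equal subclasses gave Top2a -0.73 and the TGF beta and fibrosis median 0.0393. All cells gave Id2 0.66, Nfkbia 0.13, Dnajb1 1.09, Acta2 -1.36, Tagln -1.61, Myl9 -1.72, Hk2 1.74, the complement median -0.43 and the contractile median -1.46.

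By the same criteria for after against before IR, the whole mesenchyme baseline gave Gm42726 0.59, AY036118 2.29, H2-Ab1 2.44, Cd74 2.19, Lepr 0.20, Id2 -0.0391, Cdkn1a -1.13, Dusp1 -1.94, Hk2 -0.57, the complement median 0.40 and the immediate early median -2.01. Against that baseline within lamina propria cells, Gm42726 was 0.73, AY036118 2.22, H2-Ab1 1.37, Cd74 0.21, Lepr 1.17, Dusp1 -2.23, Hspb1 -0.53, the complement median 0.0718 and the immediate early median -1.37, but Id2 (2.04), Cdkn1a (0.16) and Hk2 (2.28) kept the sign of the result. The B or plasma share gave H2-Ab1 1.79, a sign set by the subtraction, which left no UMI of H2-Ab1 before IR. Cd74 had no value since no UMI was left in either library. All cells gave Lepr 0.22, Id2 -0.19, Col14a1 0.36, Cxcl12 0.30, Isg15 -0.0852, Hspa1b -0.33, Tgfb3 0.0696, Hk2 -0.0611 and medians of 0.96 for complement, -0.61 for immediate early, -0.60 for cell cycle and -0.0535 for glycolysis genes. The values over all cells mix classes by construction, and for the other settings the cause was not tested.

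Of 1360 alternative values of 85 named gene results before IR against whole mesenchyme, 733 stayed within the counting interval of the result, 610 left it and 17 turned by those criteria, in 14 results. After against before IR, of 1461 values for 86 results, 952 stayed, 484 moved and 25 turned, in 15 results. Of 272 list medians in the first comparison 210 stayed, 58 moved and 4 turned, and of 288 in the second 223, 57 and 8. Smaller values also changed sign and are counted among those that stayed or moved. These were 21 gene values in 11 results and 17 list medians in 6 lists in the first comparison, and 49 in 24 and 4 in 2 in the second. Most of the gene values came from all cells (8 and 18), the whole mesenchyme baseline (13 in the second, and 10 within lamina propria cells) and, in the first, lamina propria cells alone (5) or equal subclasses (5). Against the whole mesenchyme baseline H2-K1 became 0.83, H2-D1 0.72, Bmp4 0.72 and the class I median 1.22, or 0.40, 0.37, 0.20 and 0.98 within lamina propria cells, and in lamina propria cells alone Igf1r before IR became -0.42. TMM factors turned Il33, Lpl and Eno1 after IR to 0.0679, 0.10 and 0.0844.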

Other observations

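The comparison of myeloid-like cells was chosen after the data were seen, with the rule for named genes used in fibroblast-like cells except the check by subclass.

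The genes with the highest and lowest ratios in myeloid-like cells after against before IR were listed, 12 of each, and no gene group was tested in them. The chemokine gene Ccl17 was 52.6-fold higher (41.0 to 68.5) after IR, at 438 against 8.33 CPM, and the eosinophil-associated ribonuclease gene Ear2 13.2-fold (10.2 to 17.2). Mmp12, Ccl24, Mmp9 and Mmp13 were higher by 7.02, 5.43, 4.11 and 3.32 on the log2 scale, but they lead cluster 8, which held 448 of the 523 myeloid-like cells after IR, so they are not independent of the clustering. Among the 12 lowest were the chemokine gene Ccl5 (0.0800-fold, 0.0658 to 0.0964), the chemokine receptor gene Ccr2 (-3.04), Ly6c2 (-2.81) and Plac8 (209 against 1480 CPM). Ccr2 and Ms4a4c lead cluster 2, which held 1161 myeloid-like cells before IR and 33 after. Cycling myeloid-like cells (cluster 13, led by Pclaf, Birc5 and Top2a) numbered 219 before and 2 after. Lepr in myeloid-like cells was 11.2 against 11.1 CPM.

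Of the 12 genes with the highest ratios in fibroblast-like cells after IR, 9 were also higher in myeloid-like cells, 8 of them by 2-fold, and 3 were lower. Igfbp7 was higher there by 4.87, Scand1 by 4.36, Nme2 by 3.19 and Mt2 by 3.19, while Gm15056 stood at -2.59, Hp at -1.35 and Hist1h2ap at -0.27. Of the 12 lowest, 11 were also lower in myeloid-like cells, only 6 of them by 2-fold, and Creb5 was higher by 0.56. Over the whole library before IR, 0.114% of UMIs lay in barcodes that were cells of the library after IR alone. Within the library before IR, 89.1% of the Saa3 UMIs of fibroblast-like cells lay in cluster 6. An epithelial-like cluster led by defensin genes held 1, 3 and 8 cells of the whole mesenchyme, before IR and after IR libraries, at a median of 61038.5 UMIs per cell.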
